A study of Zea mays with 6 samples.

How the data were processed

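Messenger RNA was sequenced from developing ears of maize (Zea mays) at a length of 2 to 3 mm. Libraries came from wild-type plants of the B73 inbred line and from ra3;tpp4 double mutants, with 3 replicates of each. The series design calls the replicates biological, and all plants were field-grown. Total RNA was extracted with a column kit and turned into libraries with a Kapa mRNA kit, per the labels' protocols.

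The deposited values are raw counts per gene ID, 1 file for each library. The submitters' processing notes name Trimmomatic 0.36 for read trimming, HISAT2 2.1.0 for alignment, HTSeq for counting and the B73 RefGen_v4 build. The annotation release, the strand setting and the parameters are not given in the sources used here, so reads of overlapping or antisense genes may be shared or lost in ways that cannot be seen. Each file ends with 5 HTSeq lines for records given to no gene (no feature, ambiguous, low alignment quality, not aligned, alignment not unique). These lines stayed out of library sizes and tests. The line for alignments that were not unique may count alignments and not reads. Reads from near-identical gene copies go to that line, so counts of such genes are uncertain.

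The files hold 46272 gene IDs, of 4 kinds: 44146 that start with Zm00001d, 1798 with ENSRNA (Ensembl's prefix for non-coding RNA genes), 174 with GRMZM and 154 with zma-MIR (microRNA precursors). The files do not pair the IDs with gene names. The RefSeq gene table at hand, for the assembly Zm-B73-REFERENCE-NAM-5.0, matched 153 IDs, all of them microRNA precursors, and none of the Zm00001d, ENSRNA or GRMZM IDs. Names were not guessed from IDs. For this reason ra3 and tpp4 were not matched to a gene ID, the check of the labels through the mutated genes was not made, and the 26 gene lists fixed by symbol and description were not tested. Calls per chromosome were not analysed here either.

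Total counts over gene IDs ran from 19291332 to 26752609 per library. A low count carries its counting error: intervals for single-library shares are 95% Wilson intervals, intervals for summed counts are exact Poisson intervals, and both cover counting error only.

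The test was edgeR 4.0.16 (quasi-likelihood F test, robust, otherwise default settings) on the counts as deposited, in R 4.3.3. IDs with low counts were removed with filterByExpr, which left 21127. Libraries were scaled by TMM. The 6 libraries entered 1 fit of genotype with WT as the reference. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are ra3;tpp4 over WT, and their standard errors were derived from the fold change and its F statistic. On simulated data for this comparison, with 20937 IDs tested and known changes, the test called 75 of 98 IDs changed 2-fold and 93 of 99 changed 4-fold, and 22 of its 190 calls were IDs that had not been changed, a larger share than the threshold allows.

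The test, the filter and the rule for named features were fixed before the data were examined. The rule took the largest changes in each direction among calls with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, and asked for a description. Descriptions could not be matched, so that demand was dropped once the data were at hand, and fewer IDs are named than the rule planned. The rule without descriptions left 189 higher and 103 lower IDs, of which 2 per direction are named. The tested microRNA precursors and a few others with low counts were added after their values were seen, because they are the features that have names. Tests on the 4 kinds of ID and the split of the ENSRNA IDs by number were also chosen after seeing the data. They used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1), adjusted over the 4 kinds.

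Alternatives were DESeq2 1.42.0, limma-voom, 2 other scalings, other filters, other edgeR fits, the replicate number as a block, leaving out each library, and leaving out ENSRNA IDs. Single values were compared by an exact permutation test, two-sided, which cannot go below p = 0.1 with 3 libraries against 3. Random lists and placements used Python 3.11.15 with numpy 2.4.6.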

Results

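RNA-seq counts were obtained from young ears of wild-type (WT) maize and of ra3;tpp4 double mutants, with 3 libraries per genotype. RAMOSA3 (ra3) encodes a trehalose-6-phosphate phosphatase that restricts branching of maize inflorescences, and tpp4 encodes another enzyme of the same family. The comparison asks how gene expression in the developing ear differs between the double mutant and WT. WT libraries held 25815984 to 26752609 counts over gene IDs and ra3;tpp4 libraries 19291332 to 25254164. A count was present for 29851 of the 46272 gene IDs in at least 1 library.

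Of 21127 IDs tested, 310 were called between ra3;tpp4 and WT, 194 of them higher and 116 lower in the mutant (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 change was 0.74 for the higher IDs and -1.27 for the lower IDs, and 183 of the 310 changed by less than 2-fold. Changes of at least 2-fold numbered 62 higher and 65 lower, and 29 of those 65 were ENSRNA IDs. Without ENSRNA IDs they numbered 62 higher and 36 lower, and the median log2 change of the lower IDs was -0.84. All 310 had mutant libraries that did not overlap the WT libraries, as did 19.6% of all tested IDs, where chance gives 10%. The count moved by over 1.5 times without any of 5 libraries: it was 132, 96 and 58 without WT replicate 1, 2 and 3, and 144, 471 and 331 without ra3;tpp4 replicate 1, 2 and 3. DESeq2 called 817 IDs, including all 310.

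The largest fall by the naming rule was that of Zm00001d022193, which dropped 17.5-fold, from 113 ± 28.5 CPM in WT to 6.53 ± 2.35 CPM in ra3;tpp4 (SD, n = 3 each). Its log2 change was -4.13 (SE 0.335, edgeR adjusted p = 0.0127). Since ra3 and tpp4 were not matched to an ID, whether Zm00001d022193 is a mutated gene was not checked. Its ID number lies 40 above the end of a stretch of 100 consecutive tested IDs that held 11 calls, where the mean was 1.34. ENSRNA049478590 fell 13.9-fold, from 450 ± 12.3 CPM to 32.2 ± 9.56 CPM (SD, n = 3 each), and supplied 29.4% of the fall in the share of counts taken by ENSRNA IDs. Its log2 change was -3.80 (SE 0.225, edgeR adjusted p = 0.00329). Among the IDs that rose, Zm00001d036653 went from 0.303 ± 0.112 CPM to 3.95 ± 1.18 CPM (SD, n = 3 each), a 12.8-fold change with 5 to 11 counts in the WT libraries and 66 to 107 in the mutant libraries. Its log2 change was 3.68 (SE 0.413, edgeR adjusted p = 0.00344). Zm00001d021386 rose 5.38-fold, from 3.92 ± 0.995 CPM to 21.0 ± 8.37 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.0356. Its adjusted p was 0.184, 0.104 and 0.13 without WT replicate 1, 2 and 3, 0.0856 without ra3;tpp4 replicate 1 and 0.105 with no filter on low counts, in a range of 1.1e-14 to 0.184 over 16 alternatives, while its log2 change stayed between 2.16 and 2.71 in all 16.

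**Figure D1:**
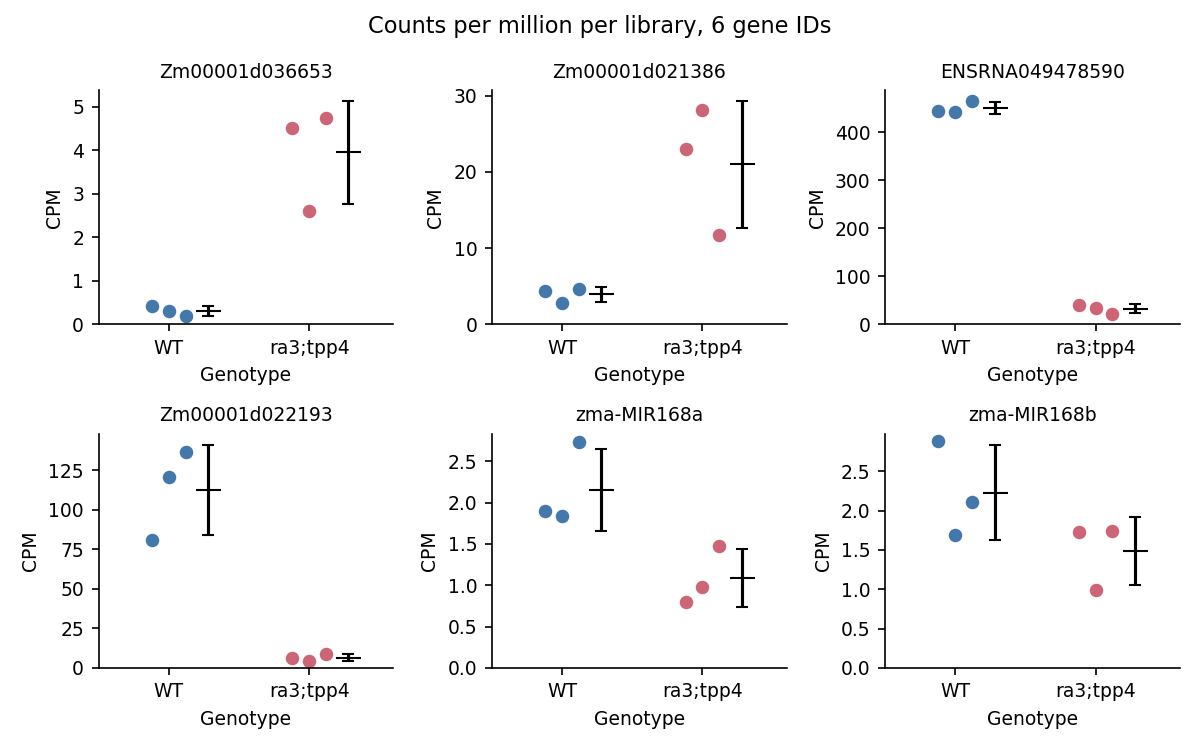
CPM (linear axis from 0) of 6 gene IDs, with 1 point per library and the mean ± SD of each genotype. The 4 called IDs have no overlap between genotypes, which the naming rule required, with WT and ra3;tpp4 means of 113 and 6.53 CPM for Zm00001d022193. The points of zma-MIR168a, which was not called, do not overlap either, while those of zma-MIR168b overlap.

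Calls were counted for each kind of ID. Of 20870 tested Zm00001d IDs, 194 were higher and 86 lower in ra3;tpp4. Of 220 tested ENSRNA IDs, which stand for non-coding RNA genes, 29 fell and 0 rose in edgeR, with 83 lower and 0 higher at an unadjusted p under 0.05. DESeq2 called 60 ENSRNA IDs lower and 0 higher, and limma-voom 42 lower and 0 higher. All 29 fell by at least 2-fold, with a median log2 change of -1.85. Camera estimated a correlation of 0.179 among the 220 ENSRNA IDs. They are thus not independent, and these counts may overstate the number of separate changes. Of 31 tested GRMZM IDs, 1 fell and 0 rose, with 4 lower and 0 higher at an unadjusted p under 0.05. DESeq2 called 2 of them lower and 0 higher. Without ENSRNA IDs the calls were 194 higher and 87 lower.

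**Figure D2:**
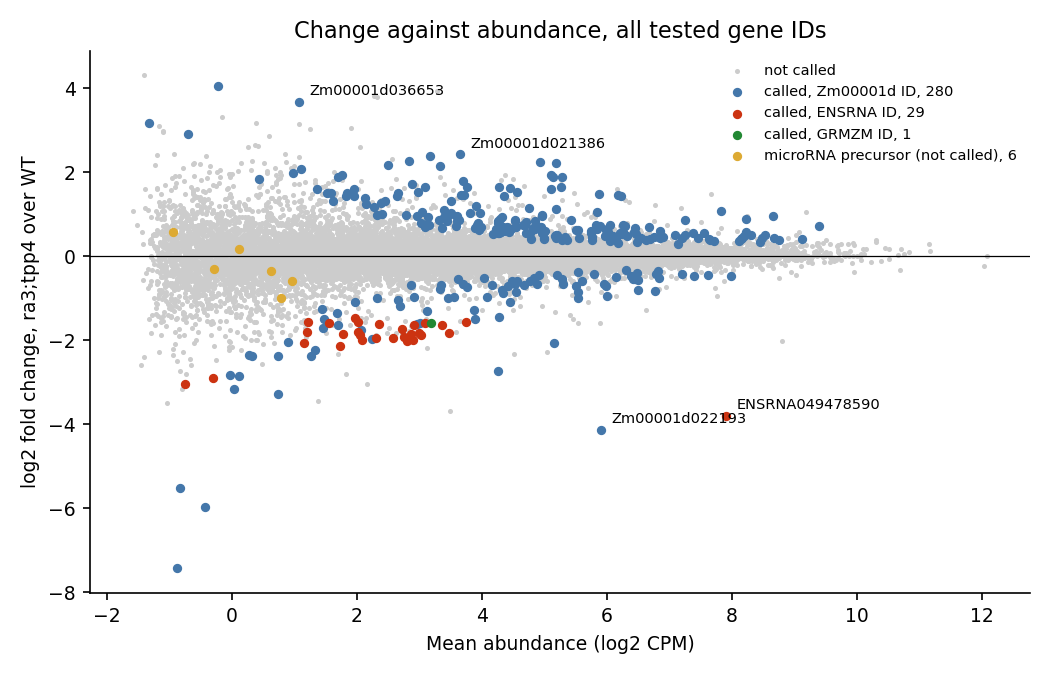
The log2 fold change of ra3;tpp4 over WT against mean abundance in log2 CPM, 1 point for each of the 21127 tested IDs, with called IDs coloured by kind. The 29 called ENSRNA IDs lie below 0, while called Zm00001d IDs lie on both sides (194 above and 86 below).

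The libraries also differed in where their records went. Alignments that were not unique made up 21.0% ± 1.51 (SD, n = 3) of all lines in WT and 13.1% ± 2.12 (SD, n = 3) in ra3;tpp4, and every mutant library lay below every WT library. This is the most extreme split that 3 libraries against 3 can give (exact permutation test, two-sided, p = 0.1, the smallest possible). The share assigned to gene IDs was 66.8% ± 1.78 in WT and 76.5% ± 1.21 in ra3;tpp4 (SD, n = 3 each). Records without an alignment made up 5.54% to 6.14% of all lines in the WT libraries and 1.57%, 5.39% and 4.62% in ra3;tpp4 replicates 1, 2 and 3, again with every mutant library below every WT library (exact permutation test, two-sided, p = 0.1). Since these shares divided by genotype, effects of library preparation on calls of any kind of ID cannot be told apart from genotype.

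**Figure D3:**
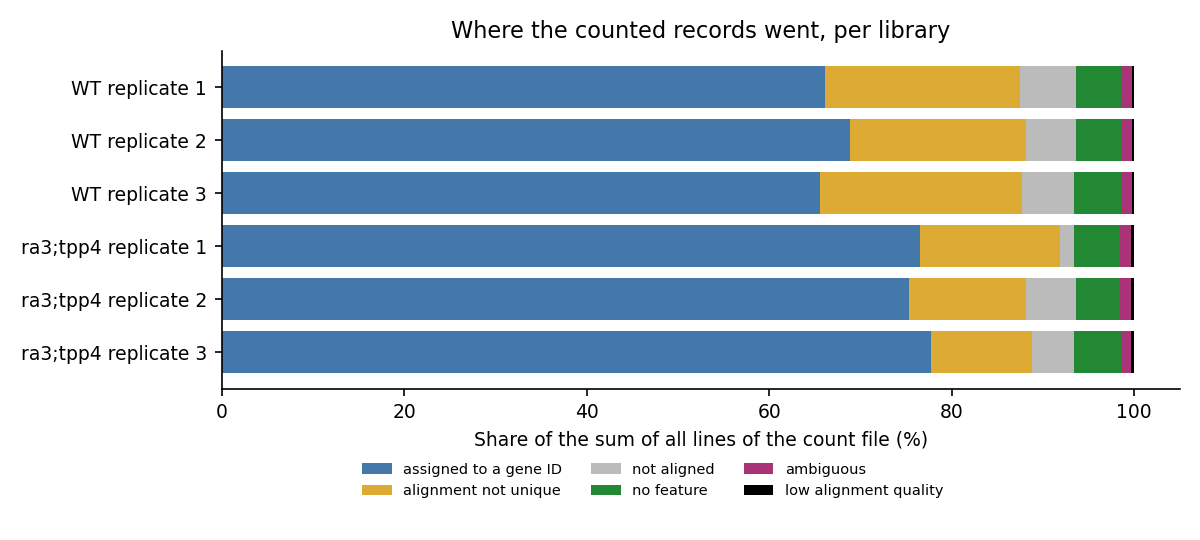
Share of all lines of each count file, in percent, that was assigned to a gene ID or to 1 of HTSeq's 5 other categories, 1 bar per library. The part of alignments that were not unique is smaller in every ra3;tpp4 bar than in every WT bar, where it is 19.3% to 22.2%.

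Over the 220 tested ENSRNA IDs the median log2 change was -0.44 (quartiles -1.60 and -0.06). The IDs were divided at the middle of their ID numbers, a boundary that uses neither calls nor fold changes, though dividing by number was chosen after the calls were seen. The 110 with the higher numbers had a median of -1.60 (quartiles -1.84 and -0.58) and held all 29 edgeR calls. The other 110 had a median of -0.18 (quartiles -0.40 and 0.02) and 0 calls in edgeR, DESeq2 and limma-voom, with 6 lower and 0 higher at an unadjusted p under 0.05 in edgeR. Of these 110, 78 had a log2 change below 0, against 98 of the 110 with the higher numbers. The share of gene counts in all ENSRNA IDs was 0.216% ± 0.0317 in WT and 0.0723% ± 0.0194 in ra3;tpp4 (SD, n = 3 each), a WT level 2.99 times the mutant level. The 2 most abundant IDs made up 67.7% of that fall, and without them the shares were 0.0980% ± 0.00795 and 0.0516% ± 0.0121 (SD, n = 3 each), a ratio of 1.90. The share of alignments that were not unique was lower in the same 3 libraries. By camera with a preset correlation the ENSRNA set was lower than other IDs (adjusted p = 3.2e-31), a call that was lost with an estimated correlation (adjusted p = 0.0589). By fry, which does not compare the set with other IDs, it fell at adjusted p = 0.0348. The GRMZM set was lower at adjusted p = 0.00071 with the preset correlation. It was not called with an estimated correlation (adjusted p = 0.0947) or by fry (adjusted p = 0.0553). The count of 29 was 8, 5 and 4 without WT replicate 1, 2 and 3, and 39, 26 and 36 without ra3;tpp4 replicate 1, 2 and 3. The Zm00001d IDs make up 20870 of the 21127 tested, so a test of that set against the rest mainly restates the lower values of the ENSRNA IDs and is not given; their median log2 change was -0.00069 and fry did not call them (adjusted p = 0.316).

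**Figure D4:**
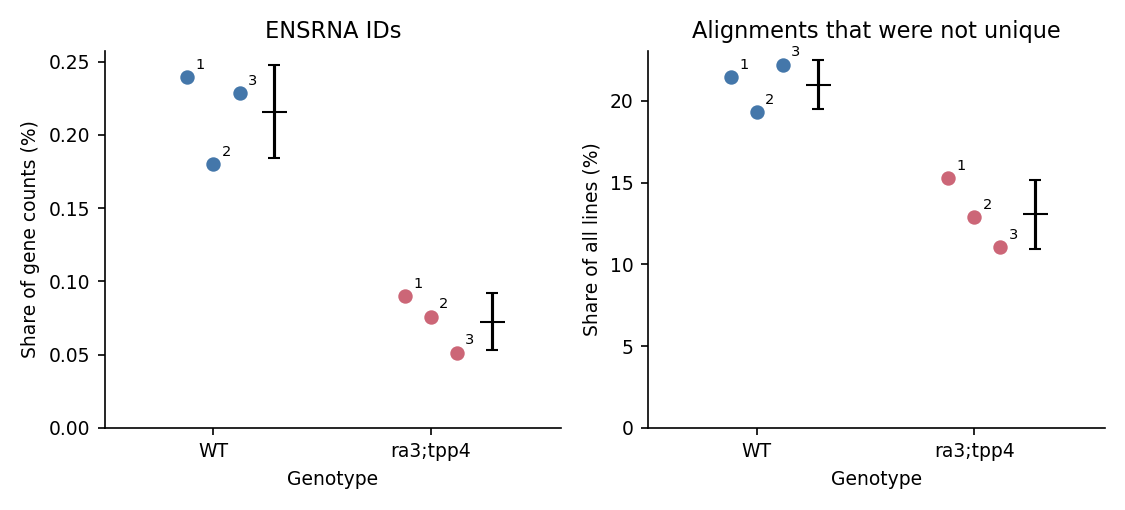
Left, the share of gene counts in ENSRNA IDs, and right, the share of all lines that were alignments not unique, both in percent, with 1 point per library (numbers are replicates) and the mean ± SD of each genotype. All 3 ra3;tpp4 points lie below all 3 WT points in both panels.

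MicroRNA precursors were the IDs with names. Of 154, 31 had a count and 6 were tested, and edgeR called 0 of them, with 1 lower at an unadjusted p under 0.05; DESeq2 and limma-voom called 0. These values are reads on precursor transcripts and say nothing of mature microRNA levels. Among the 6 tested, the largest difference was in zma-MIR168a, precursor of the microRNA that targets ARGONAUTE1 transcripts, with 2.16 ± 0.499 CPM in WT and 1.09 ± 0.350 CPM in ra3;tpp4 (SD, n = 3 each). Its log2 change was -0.99 (SE 0.363, edgeR adjusted p = 0.252), and every mutant library lay below every WT library. The other copy, zma-MIR168b, stood at 2.23 ± 0.604 CPM in WT and 1.48 ± 0.434 CPM in ra3;tpp4 (edgeR adjusted p = 0.525). Reads that fit both copies may be missing from both counts. The precursors zma-MIR159a (log2 change -0.35, of the family that targets MYB factors) and zma-MIR166a (-0.30, of the family that targets class III homeodomain-leucine zipper genes) did not pass the test, with edgeR adjusted p of 0.732 and 0.820. Nor did zma-MIR160d (0.58) and zma-MIR167d (0.16), of families that target auxin response factors, with edgeR adjusted p of 0.670 and 0.898. As a set the precursors were not called (camera adjusted p = 0.243, and adjusted p = 0.416 with an estimated correlation; fry adjusted p = 0.127).

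Precursors of the MIR156 and MIR172 families, which are known for roles in maize inflorescence architecture, were close to the detection limit. The 11 MIR156 IDs together held 7 counts in all 6 libraries. Of 4 MIR172 IDs only zma-MIR172e, the tasselseed4 locus, which limits the growth of spikelet and floral meristems, had counts. It had 6 in WT (exact Poisson interval 2.20 to 13.1), with 2 in each library, and 1 in ra3;tpp4 (0.0253 to 5.57), so every mutant library lay below every WT library. Given the library sizes, the split of these 7 counts did not pass an exact binomial test (two-sided, p = 0.131, for counting error only), and the exact permutation test gave p = 0.1, the smallest possible.

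By correlation across IDs, libraries of the same genotype resembled each other only a little more than libraries of different genotypes. Across the tested IDs, which are not independent replicates, the correlation of log2 CPM was 0.975 to 0.989 within genotypes and 0.965 to 0.983 between them. The first principal component, with 37.2% of the variance, separated the genotypes, and ra3;tpp4 replicate 2 lay apart from the other mutant libraries at 49.3 against 14.0 and 14.2. The next component, with 28% of the variance, did not follow genotype: WT replicate 1 and ra3;tpp4 replicate 2 lay at 29.3 and 31.3, WT replicates 2 and 3 at 0.631 and -0.999, and ra3;tpp4 replicates 1 and 3 at -26.9 and -33.3. Chi-square per degree of freedom was 5.33 to 16.3 in pairs within a genotype and 10.7 to 27.8 in pairs between genotypes. No 2 libraries thus agreed within sampling noise, so all 6 were treated as separate samples.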

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

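The edgeR 4 bias-adjusted fit and the fit without ENSRNA IDs were chosen after seeing the data. Of the 310 called IDs, 0 changed direction in any alternative that tested them. A reversal could hardly occur, since no called ID had overlapping genotypes and the alternatives reuse the same counts. The filter at a CPM of at least 1 left 9 of them untested, and the fit without ENSRNA IDs left 29 untested. The count of calls, 310 (194 higher, 116 lower), was 817 (492 and 325) in DESeq2 and 511 (298 and 213) with no filter on low counts. Leaving out each library in turn gave 58 to 471 calls, 34 to 262 higher and 24 to 209 lower, and 4 to 39 ENSRNA IDs lower in place of 29; fewer libraries enter those fits, and why WT replicates weigh so much was not tested. ENSRNA calls were 60 in DESeq2 and 47 in the bias-adjusted fit; the cause was not tested. Other scalings gave 314 and 326 calls, limma-voom 341, and the fit without ENSRNA IDs 263. The replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.181, -0.123 and 0.154 in their deviations from the group means, and 2 of 6 libraries correlated best with their own number. With the number as a replicate block, 290 IDs were called, 221 of them shared with the 310, and Zm00001d021386 was not called (edgeR adjusted p = 0.116, log2 change 2.36). Of the named IDs, Zm00001d022193 and Zm00001d036653 were called in 16 of 16 alternatives, ENSRNA049478590 in the 15 that tested it, Zm00001d021386 in 10 of 16, and the 6 microRNA precursors in none that tested them. The planned tests of gene lists, of ra3 and tpp4 and of calls per chromosome gave no value, since names and positions were not matched to the IDs. Depth limits statements on precursors with fewer than about 10 counts per library.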

Other observations

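All tests in this part were chosen after the results had been seen. Calls were not spread evenly over the numbers in the Zm00001d IDs. The densest 100 consecutive tested IDs, numbers 21952 to 22153, held 11 calls where the mean was 1.34, and the highest count in any stretch that did not overlap it was 8. Of the 11, 8 were lower in ra3;tpp4, against 78 lower and 191 higher among the other called Zm00001d IDs. Over all IDs, 3 had at least 10 counts in every WT library and at most 1 in every mutant library, and 2 of them lay within 100 numbers of Zm00001d022193; 0 had the opposite pattern. Without the stretch and Zm00001d022193, the calls were 191 higher and 107 lower.

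Random placement of the 280 Zm00001d calls reached 11 in a stretch with a permutation p of 2e-04 (10000 placements), which argues against chance placement. DESeq2 calls gathered in an overlapping stretch, numbers 21985 to 22184, with 19 calls (permutation p = 1e-04, the smallest the placements can give). The DESeq2 calls come from the same libraries and include all 310 edgeR calls, so they are not separate evidence. Whether neighbouring numbers are neighbouring genes is not given in the sources used here. If they are, a candidate explanation is a segment linked to a mutant allele that does not come from B73, whose reads map less well to the B73 genome. The excess of lower calls (Fisher's exact test, two-sided, p = 0.00428) does not decide this, since the test treats neighbouring calls as independent. Of 249 runs of 11 consecutive calls outside the stretch, 1 also held 8 lower calls, the highest number in any run. These runs overlap each other and take in IDs just beside the stretch, such as Zm00001d022193, so they do not decide it either. Real expression differences carried by such a segment and effects of the mutations on nearby genes were not tested and stay open. The same holds for reads lost between near-identical neighbouring copies. Neither ra3 nor tpp4 was matched to an ID, so Zm00001d022193 or an ID in the stretch could be a mutated gene.

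The ENSRNA IDs formed the other pattern. Their median log2 change of -0.44 lay below the range of -0.07 to 0.07 given by 10000 lists of Zm00001d IDs matched on abundance. Zm00001d IDs of like abundance thus did not share the fall, which argues against library depth alone. For the 110 with the lower numbers, the median of -0.18 also lay below its matched range of -0.11 to 0.12. Each list was drawn ID by ID, so all matched ranges here are too narrow for IDs that vary together. Levels of the ENSRNA IDs also shifted between libraries of 1 genotype: the median difference lay outside the matched range in 5 of the 6 pairs within genotypes. Pairs of 1 genotype share libraries, so the 6 are not independent. With the IDs divided at the middle of their numbers, 5 of 6 pairs lay outside among the 110 with the higher numbers, and 1 of 6 among the other 110. In the 110 with the higher numbers, the median log2 differences were -0.20, 0.03 and 0.18 for the WT pairs. For the ra3;tpp4 pairs they were -0.41, -0.69 and -1.17 (replicate 3 minus replicate 1), so the large shifts lay among the mutant libraries. A candidate explanation is an RNA class carried over in amounts that differ from library to library, such as RNA without a poly(A) tail. Which RNAs these IDs stand for was not tested. A lower level of these RNAs in ra3;tpp4 ears cannot be told apart from such carry-over. All mutant libraries lay below all WT libraries for 93 of the 220 IDs (5% by chance if IDs were independent, which they are not). No value separates genotype from library preparation.

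For the 310 calls, the 10 splits of the 6 libraries are too few to reach a share under 0.05: only the real split, 1 of 10, gave as many. The highest of the other splits gave 0 calls in edgeR, the only tool run on the splits. The other splits had 296 to 1714 IDs at an unadjusted edgeR p under 0.05, against 2825 in the real split. Each of them mixes the genotypes within its groups, so the genotype difference adds to the spread within groups and lowers the calls. These splits therefore do not measure what chance alone gives.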
